A study of Ooceraea biroi with 2 samples.

How the data were processed

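The series holds single-nucleus RNA measurements of antennal clubs from pupae aged 14 days, in 1 group with 2 replicate libraries. Per the labels, nuclei were extracted with a custom protocol for insect tissue and libraries were made with the 10x Genomics 3' v3.1 kit. The deposited matrices hold UMI counts per gene and barcode that the authors made with Cell Ranger 7.0.1, per the file headers and the labels. They list a filtered set of barcodes with no normalization. The genome build, the annotation and the handling of introns are not stated. The files hold 14167 genes, of which 13289 have a LOC identifier and 662 are chemosensory genes in 1 block of consecutive entries, apart from the other genes.

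Of the gene names, 13337 were found in the reference table of assembly Obir_v5.4, which gives no product names for them and none of the odorant receptor names. Cell types and gene groups had been fixed as patterns of symbols and product names before the data were examined. Only symbols could be matched. Of 11 lists of cell type markers, 2 matched: olfactory sensory neurons with 1 gene (Orco) and ionotropic receptor neurons with 6 genes. The lists for neurons, mechanosensory neurons, sensillum support cells, glia, epidermis, hemocytes, muscle, trachea and fat body or oenocytes matched 0 genes. Of 14 gene lists, 4 matched: odorant receptors without Orco (573), gustatory receptors (26), ionotropic receptors without markers (22), and odorant-binding and chemosensory proteins (34). The other 10 matched 0 genes and gave no result: xenobiotic enzymes, axon guidance, transmitter synthesis, neuropeptides, transmitter receptors, ion channels, cuticle, cilium, RNA 3' ends and decay, and chromatin modifiers. With Orco as the only olfactory marker, the planned class of olfactory neurons could not be named. It was replaced by the Orco clusters, with limits set after the data were seen: at least 200 Orco CPM and a median of at least 1500 UMIs per nucleus. The other clusters stood in for the planned non-neuronal classes and can hold neurons.

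Nuclei with at least 500 UMIs, at least 300 genes and at most 5% mitochondrial UMIs were kept, which left 13852 and 13528. The smallest barcodes had 950 and 933 UMIs. Scrublet marked 0% of nuclei as doublets in both libraries, so none was left out, and leaving out the 8% with the highest scores was added as an alternative. Counts were scaled to 10000 per nucleus, log-transformed, and 3000 variable genes outside the gene lists gave 30 principal components, 15 nearest neighbours and Leiden clusters at resolution 1 for both libraries together. Orco was not among the variable genes, and 2 markers of ionotropic receptor neurons were. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, scikit-learn 1.9.0, igraph 0.11.9 and matplotlib 3.10.9 were used.

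A receptor was called in a nucleus at 2 or more UMIs, and at 1, 3, 5 and 10 as alternatives. The top receptor is the one with most UMIs, without ties. Intervals of shares were exact binomial at 95%, and 3 counts were taken as the limit that a count of 0 allows, both for counting error only. Genomic arrays could not be built, because the receptors have no coordinates or strand. They were replaced by 32 runs of consecutive receptors in the gene list, 21 of them with 3 or more members. The genes with coordinates followed chromosomal order (13293 genes, 0 out of order), but whether the chemosensory block does so could not be checked. A run ends only at another chemosensory gene. Shuffles (100) kept each receptor's number of nuclei and each nucleus's number of receptors. The next-minus-previous difference was taken per run or receptor with at least 10 nuclei in each library, oriented by its sign in the other library, and tested over runs with 100000 sign flips. The planned comparisons by strand of neighbours and by gap length were not possible. The code was tested on simulated nuclei, where the planted direction was recovered in 16 of 16 runs.

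For genes, UMIs were added per class and library into 24 sums of 12 classes: the Orco clusters, the low-UMI cluster and 10 other clusters with at least 50 nuclei in each library. The sums were fitted with edgeR 4.0.16 in R 4.3.3 (TMM, filterByExpr, robust quasi-likelihood F test, library as a block, 11 residual degrees of freedom, common biological coefficient of variation 0.0640). Benjamini-Hochberg adjusted p under 0.05 was the threshold. The low-UMI cluster was in the fit and in no contrast. Sums of 1 library share its preparation, and the spread is estimated from the classes fitted together. Lists were tested with camera and fry of limma 3.58.1. In simulated sums for the contrast of Orco and other clusters, with 7554 genes tested, edgeR recovered 98.9% of 92 tested genes changed by a fold of 2 and 100% of 91 changed by a fold of 4, with 11 false calls (5.70% of calls). All classes were drawn from 1 common profile apart from these changes, so the other clusters did not differ as they do in the data. The simulation therefore checks the code and does not give the error rates of the real contrast. DESeq2 1.42.0, other size factors, no filter, no replicate block, a limit of 1000 UMIs and 1 sum of all other clusters as reference were alternatives.

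The rule for named genes was fixed before the data were examined: Orco in every class, the 10 receptors that are top in most nuclei and in both libraries, the 5 runs with most nuclei of 2 or more receptors, up to 3 genes per list and contrast with the largest fold change among those past the threshold with at least 50 UMIs and 1 direction in both libraries, at most 10 genes in all for contrasts other than the first, and every member behind a count of 5 or fewer. Genes outside it are marked in the text.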

Results

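Nuclei were measured from the antennal clubs of 14-day-old pupae of the clonal raider ant Ooceraea biroi. The club is the enlarged tip of the antenna, where most olfactory sensilla of ants lie. There was 1 group with 2 replicate libraries. Library 1 held 13856 barcodes with 45744156 UMIs in all, with a median of 3039 UMIs and 1283 genes per barcode. Library 2 held 13529 barcodes with 43612260 UMIs, with medians of 2989 UMIs and 1273 genes. Across 12209 genes the UMI sums of the libraries had a Pearson r of 0.998 and a Spearman rho of 0.997, where genes are not independent replicates. The series title concerns odorant receptor choice, which is the expression by a sensory neuron of 1 or a few receptor genes out of a large family. With a single group, the comparisons were between clusters of nuclei and between receptor genes. Every value below with ± is a mean and SD over the 2 libraries (n = 2) unless stated otherwise.

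Clusters with Orco, the coreceptor that insect odorant receptors need to form a channel, held most nuclei of both libraries. The 12 clusters with at least 200 Orco CPM and a median of at least 1500 UMIs per nucleus are called Orco clusters here, where CPM stands for the UMIs of a gene or gene group scaled by all UMIs of its cluster or class. They held 18394 nuclei, 67.2% ± 1.39 of those kept, and had 331 ± 11.3 Orco CPM. The 17 other clusters held 4691 nuclei, 17.1% ± 0.607, with 92.5 ± 9.84 Orco CPM. A single cluster of 4295 nuclei, 15.7% ± 1.99, had a median of 1069 UMIs and is called the low-UMI cluster. Odorant receptor genes took 17683 ± 140 CPM in the Orco clusters and 5962 ± 74.4 in the other clusters, which had more UMIs per nucleus (medians 4012 and 4062 against 3213 and 3206). At least 1 Orco UMI was found in 55.2% and 57.0% of nuclei of the Orco clusters and in 26.9% and 28.6% of the other clusters, so a nucleus could not be placed by its own Orco count. Orco was the only marker of olfactory neurons that could be matched, which is too few to name a cluster a neuron type.

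**Figure D1:**
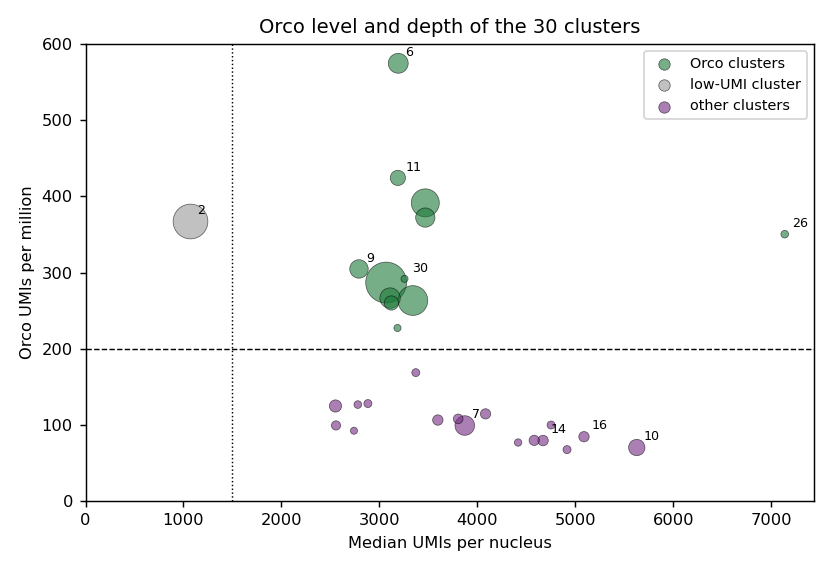
Orco CPM (vertical axis) against the median UMIs per nucleus (horizontal axis) in each of the 30 clusters of both libraries, with the area of a point growing with its number of nuclei. The dashed line is the limit of 200 Orco CPM and the dotted line the limit of 1500 UMIs; the low-UMI cluster lies at 368 Orco CPM and a median of 1069.

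The first comparison asked which listed genes were higher or lower in the Orco clusters than in the mean of the 10 other clusters with at least 50 nuclei in each library. Odorant receptors, the ligand-binding subunits that pair with Orco, were higher almost throughout: of 371 tested, 343 rose, 3 fell and the rest did not pass. The median log2 fold change of the list was 2.32. The largest changes were those of Or5-P2 (log2 fold change 4.66, SE 0.41), Or5-9E125 (4.60, SE 0.37) and Or5-U18 (4.41, SE 0.35), with edgeR adjusted p of 7.97e-12, 8.64e-13 and 5.22e-13. Each was higher in both libraries than that mean, although cluster 13 had 4.90 and 30.8 CPM of Or5-P2 against 16.4 and 19.5 in the Orco clusters. The 3 that fell were Or5-9E153PSE (-2.80, SE 0.55), Or5-9E341PSE (-0.26) and Or5-9E343 (-0.26). Adjusted over the list alone, 349 rose and 4 fell, the added one being Or5-9E340 (-0.20).

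The other chemosensory lists changed in few members. Of 6 gustatory receptors tested, Gr2 (-0.97, SE 0.31) and Gr11 (-0.43, SE 0.15) fell and none rose, with a list median of -0.14. Cluster 14 weighs on both falls, with 160 and 180 CPM of Gr2 against 2.49 and 3.42 in the Orco clusters. Of Gr11 it had 4352 and 6085 CPM against 51.3 and 48.6. Several other clusters had less Gr11 than the Orco clusters, such as cluster 7 with 28.3 and 29.7. Of 10 ionotropic receptors tested, which form a separate family of sensory channels, Ir75u.1 (3.21, SE 0.42) and Ir310 (2.09, SE 0.75) rose and none fell, with a median of 0.37. Single other clusters had more of both, as Ir310 had 3.91 and 3.62 CPM in the Orco clusters but 37.4 and 20.1 in cluster 14, and Ir75u.1 had 13.9 and 13.6 but 33.9 and 39.0 in cluster 16. Of 9 odorant-binding and chemosensory proteins tested, secreted carriers made in part by support cells, Csp4 (0.24) rose and Obp59a (-0.76), Obp10 (-0.51) and Csp2 (-0.44) fell, with a median of -0.19. Single clusters weigh on these falls too. Cluster 7 had 294 and 320 CPM of Csp2 against 12.4 and 12.9 in the Orco clusters, and cluster 18 had 208 and 171 of Obp10 against 18.1 and 20.5. Some clusters had less than the Orco clusters, such as cluster 10 with 8.72 and 6.06 of Csp2 and cluster 7 with 13.8 and 10.2 of Obp10. The rise of Csp4 depended on Orco cluster 9, which had 1874 Csp CPM and the highest median mitochondrial share of the Orco clusters, 0.748%. Without it, a comparison chosen after seeing the data, all 9 fell past the edgeR threshold, Csp4 among them (-0.24), and the median was -0.52. Gr10 (-0.88) and Ir315.1 (-0.71) then also fell past it. With cluster 9 kept and adjusted over the list alone, the counts were 0 up and 2 down for gustatory receptors, 2 up and 0 down for ionotropic receptors, and 1 up and 3 down for the secreted proteins. At an unadjusted edgeR p under 0.05 they were 0 up and 3 down, 3 up and 1 down, and 1 up and 4 down. With DESeq2 the counts were 0 up and 3 down, 1 up and 0 down, and 0 up and 4 down, so the rises of 1 ionotropic receptor and of Csp4 were not called by it.

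As sets, the odorant receptors were higher than other genes with camera (adjusted p 2.29e-28 in the fit of edgeR sums, and adjusted p = 1.23e-09 with an estimated correlation), and fry gave them an adjusted p of 1.00e-13 for moving 1 way. For the gustatory and ionotropic receptors and the secreted proteins, none of the 3 set tests of the edgeR sums passed the threshold, with camera adjusted p of 0.769 for each and fry adjusted p of 0.595, 0.595 and 0.232. Over all 8438 genes tested with edgeR, 2280 were higher and 2122 lower, but genes outside the lists had taken part in the clustering, so their counts are not an independent comparison. Among them LOC105285763 (2.42) and LOC109610657 (2.42) were higher and LOC105282079 (-3.85) and LOC105279108 (-3.85) lower, chosen after their values were seen from the 300 with the smallest p. The fold change is against the mean of 10 cluster levels on the log scale, several of them near 0. With 1 CPM added to every level before the log, the differences in the 2 libraries were smaller, 3.02 and 2.84 for Or5-P2, 1.89 and 2.20 for Ir75u.1, and 0.62 and 0.75 for Ir310.

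Receptors that did not rise lay mostly in 1 stretch of the gene list. Of the 28 tested receptors that were not higher, 23 belonged to the run of 89 receptors from Or5-9E255 to Or5-9E343, where a run is a stretch of consecutive odorant receptors in the gene list. In this run 63 of 86 tested receptors rose, and in all other runs 280 of 285 did. The 29 receptors from Or5-9E315 to Or5-9E343 together took 1510 ± 11.8 CPM in the Orco clusters and 1172 ± 1.45 in the other clusters, a ratio of 1.29 ± 0.0117. For the 60 receptors before them in the run the ratio was 2.0 ± 0.118, and for the 484 receptors of the other runs 4.38 ± 0.280. This split of the run was chosen after its values were seen, and no test compared the ratios.

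The second question was how many odorant receptors a nucleus contains. Nearly all nuclei of the Orco clusters had a called receptor, but the number per nucleus at 2 or more UMIs could not be read as receptors expressed. With a receptor called at 2 or more UMIs, 97.2% ± 0.0431 of nuclei in the Orco clusters had at least 1, and 92.5% ± 0.560 of those had 2 or more, with a mean of 7.62 receptors. In simulated nuclei with 1 receptor each and free RNA at the mean receptor level of the other clusters, 84.5% already had 2 or more, with a mean of 2.84. With that free RNA alone, 83.65% of simulated nuclei had a called receptor, and 65.4% of these had 2 or more. In the other clusters 75.2% ± 0.815 of nuclei also had a called receptor, fewer than the 83.65% simulated at their mean level. The simulated shares may therefore be too high. Whether the calls in the other clusters come from free RNA or from neurons there was not tested. With nuclei of at least 1000 UMIs thinned to that number the shares were 85.6% ± 0.132 and 25.4% ± 1.31.

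At 5 or more UMIs, a limit chosen after seeing the data, the share in the other clusters fell further. Then 81.6% ± 0.127 of nuclei in the Orco clusters and 15.7% ± 0.690 in the other clusters had a receptor, or 42.1% ± 0.322 and 2.71% ± 0.306 after thinning. The Orco clusters were not alike in this. A top receptor at this limit was found in 291 of 1113 nuclei of cluster 9 and in 5297 of 6012 of cluster 1, the largest. Of the positive nuclei in the Orco clusters, 66.7% ± 0.211 still had 2 or more, with a mean of 3.01 and a median of 2 receptors. In the simulated nuclei with 1 receptor it was 0.025%. That simulation drew free RNA at 1 mean level for all nuclei. Free RNA alone then gave a receptor in 0.1% of simulated nuclei, against the 15.7% of the other clusters. It therefore cannot give the share expected for nuclei with 1 receptor at this limit. At 10 or more UMIs the share of positive nuclei in the Orco clusters with 2 or more was 42.1% ± 1.02, so the number of receptors per nucleus depended strongly on the limit.

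**Figure D2:**
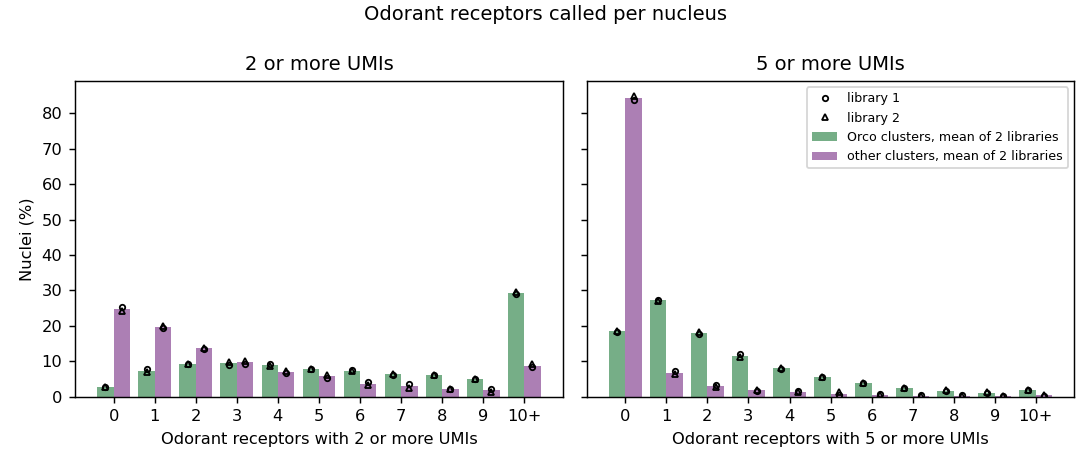
Share of nuclei (vertical axis, percent) by the number of odorant receptors called (horizontal axis), at 2 or more UMIs on the left and 5 or more on the right. Bars are means of the 2 libraries for the Orco and the other clusters and symbols the single libraries; at 5 or more UMIs 81.6% of nuclei in the Orco clusters and 15.7% in the other clusters have at least 1.

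Receptors found together in a nucleus mostly came from the same run of the gene list. Of all pairs of receptors called in the same nucleus of the Orco clusters, 77.7% ± 0.395 came from 1 run, against 19.9% ± 0.540 when receptors were shuffled among nuclei (100 shuffles, highest 20.5%). At 5 or more UMIs the share was 91.9% ± 0.483 against 16.2% ± 0.317. Pairs of directly consecutive receptors made up 8.60% ± 0.116 of the pairs at 2 or more UMIs and 20.8% ± 0.150 at 5 or more, against 0.665% ± 0.0211 and 0.662% ± 0.0186 of the shuffled ones. In the other clusters too, 71.5% and 71.7% of pairs came from 1 run at 2 or more UMIs, against 43.2% and 42.2% when shuffled. At 5 or more UMIs the shares there were 92.08% and 91.84%, against 19.47% and 20.02% when shuffled. They were thus close to the 91.9% of the Orco clusters, but rest on 219 and 198 nuclei with 2 or more receptors. When a nucleus had 2 or more receptors of 1 run, these formed an unbroken stretch in 17.7% ± 0.0960 of cases at 2 or more UMIs and in 36.5% ± 0.0579 at 5 or more, against 1.71% ± 0.0453 and 2.32% ± 0.0836 for random members of the run.

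The 5 runs with most nuclei holding 2 or more of their receptors at 2 or more UMIs were long. The run from Or5-9E255 to Or5-9E343, with 89 receptors, had 6764 such nuclei. The run from Or5-B1 to Or5-9E230 (84 receptors) had 3081, that from Or5-9E107 to Or5-9E151 (50 receptors) 1742, that from Or5-9E231 to Or5-U65 (66 receptors) 1418 and that from Or5-9E29 to Or5-9E75 (47 receptors) 1297. In the same order the numbers at 5 or more UMIs were 2367, 2375, 1321, 1025 and 987, so the lead of the first run was gone. Runs were split only by another chemosensory gene, since the receptors stand in the files apart from all other genes and without coordinates, so a run may join several genomic arrays. Receptors of 1 subfamily can also share reads, which the counts cannot separate, and such receptor values are uncertain.

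Around the receptor with most UMIs in a nucleus, called the top receptor here, the calls extended mainly to 1 side. For each receptor the side with more calls in the other library was taken as the positive one. At 5 or more UMIs the next receptor on that side was called in 50.9% ± 0.807 of nuclei and the next on the opposite side in 12% ± 0.0381. At a distance of 2 places the shares were 29.0% ± 0.476 and 6.02% ± 0.367, and at 3 places 21.6% ± 0.152 and 4.75% ± 0.677. Mean UMIs were 22.5 ± 0.525 for the top receptor, 6.79 ± 0.178 for the next on the positive side and 1.71 ± 0.0006 on the opposite side.

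**Figure D3:**
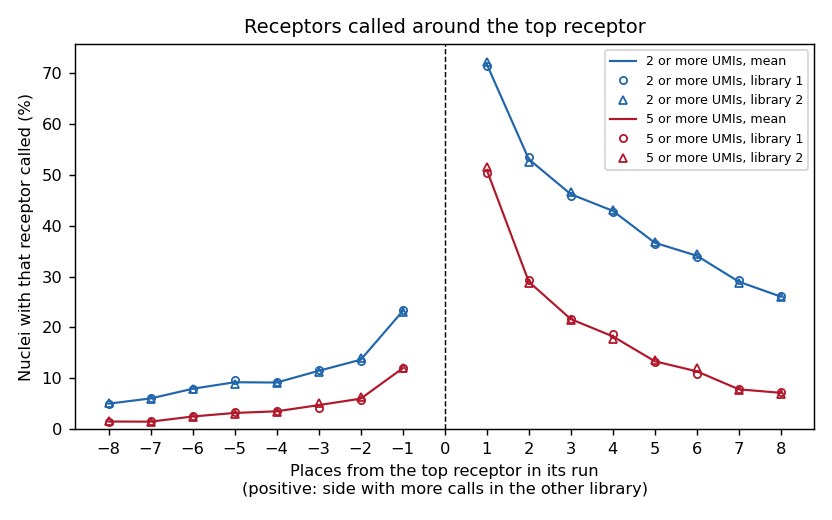
Share of nuclei in which a receptor is called (vertical axis, percent) by its distance in places from the top receptor (horizontal axis), with the positive side set for each receptor by the other library. Lines are means and symbols the 2 libraries; at 5 or more UMIs the first place holds 50.9% on the positive side and 12% on the other.

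For most receptors the libraries agreed on the side. Of 230 receptors with a difference other than 0 in both libraries and at least 10 such nuclei in each, 224 had the same sign at 2 or more UMIs, and 187 of 195 did at 5 or more. Across receptors, which are not independent replicates, the differences of the 2 libraries had a Pearson r of 0.963 and a Spearman rho of 0.949. More receptors had the previous receptor called more often (167) than the next in list order (74). For Or5-9E184 the difference between next and previous was 72.5 points in library 1 and 75.4 in library 2, and for Or5-9E218 it was 80.8 and 74.0. For Or5-9E305 it was -26.3 and -34.9 and for Or5-9E275 -26.8 and -30.6. The side depended on the limit for some receptors. Of 180 with 1 sign in both libraries at each limit, 7 had opposite signs at 2 and 5 UMIs, among them Or5-9E137, with -2.35 and -6.85 points at 2 or more UMIs and 4.76 and 22.2 at 5 or more. For Or5-E15 the difference shrank from -16.7 and -20.3 to 0 and -2.56.

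By run, the mean difference toward the side set by the other library was 28.9 points ± 0.198 over 19 runs, with the same sign in both libraries in 17 of them (two-sided permutation test by sign flips over runs, p = 3e-05). At 5 or more UMIs it was 19.8 points ± 0.0244, with 15 of 19 runs alike (permutation p = 0.00012). Calls favoured the previous receptor in the run from Or5-9E255 to Or5-9E343 (-38.1 and -42.1 points), in that from Or5-9E107 to Or5-9E151 (-30.4 and -34.3) and in that from Or5-9E29 to Or5-9E75 (-38.5 and -39.1). They favoured the next receptor in the runs from Or5-9E231 to Or5-U65 (36.8 and 34.0) and from Or5-B1 to Or5-9E230 (16.6 and 17.1). The files give no strand for any receptor, so the sides could not be translated into upstream and downstream. The planned test by direction of transcription was therefore replaced by this test of a shared side.

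**Figure D4:**
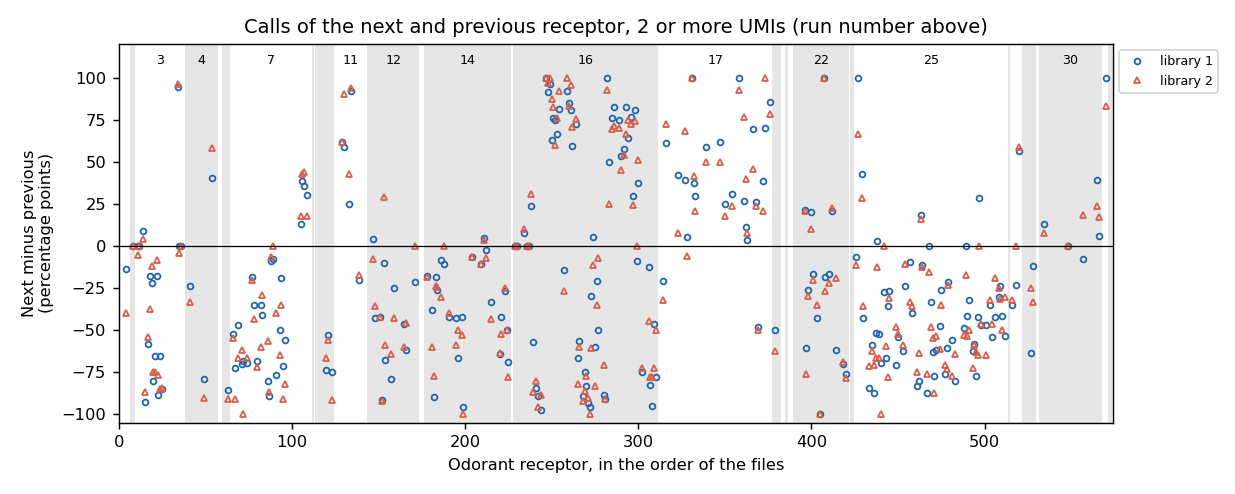
Share of nuclei with the next receptor called minus the share with the previous one (vertical axis, percentage points) for each top receptor with enough nuclei, in list order (horizontal axis), at 2 or more UMIs. Symbols are the 2 libraries and shading marks alternate runs, numbered above where they hold 15 or more receptors; the libraries had a Pearson r of 0.963.

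Most receptors of the family were the top receptor of some nucleus of the Orco clusters. Of 573 odorant receptors apart from Orco, 494 were top in both libraries at 2 or more UMIs and 464 at 5 or more. The most frequent at 2 or more UMIs was Or5-9E184, the top receptor of 250 nuclei (1.56% ± 0.159), followed by Or5-9E108 (194), Or5-9E305 (163), Or5-9E137 (158), Or5-9E275 (156), Or5-9E177 (126) and Or5-E15 (118). Or5-H6PSE was top in 105 nuclei, 0.649% ± 0.244, and Or5-9E114 and Or5-9E218 in 102 each. The numbers of these 10 at 5 or more UMIs, in the same order, were 245, 184, 136, 156, 139, 121, 73, 87, 97 and 98, so the order below the first 2 changed and Or5-E15 came last. When it was top, Or5-H6PSE had a median of 389 UMIs, against 29 for Or5-9E184 and 5 for Or5-E15. It was the only receptor called in 93.1% of the 87 nuclei where it was top at 5 or more UMIs, and Or5-E15 was in 93.2% of its 73. With so few UMIs for Or5-E15, a receptor below it could seldom reach the limit, so its share says little. The letters PSE in a name are read here as a pseudogene mark, which the files do not explain. At 5 or more UMIs, 70 receptors were never top, 35 of the 66 with PSE in the name and 35 without it. Across receptors the numbers of top nuclei of the libraries had a Pearson r of 0.924 (log2) and a Spearman rho of 0.923.

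Receptors with few list neighbours were more often alone. For the 17 receptors in runs of 1 or 2, 29.2% ± 5.27 of nuclei with such a top receptor had 2 or more receptors at 5 or more UMIs, against 65.8% ± 0.0652 for the 556 receptors of longer runs. This did not come with weaker expression, as the top receptor had medians of 30 and 26 UMIs in the short runs and 14 in both libraries in the longer ones. Or5-9E254 was among the 17, and it was the only receptor in 86.4% of the 88 nuclei where it was top. The comparison was chosen after seeing the data and rests on few receptors. Over both libraries Or5-9E76, Or5-9E254 and Or5-9E77 were top in 91, 88 and 48 nuclei, where the short runs held 169 and 155 nuclei in the 2 libraries.

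Clusters made without any receptor count still differed in receptor subfamily, taken as the letters in the receptor's name. The variable genes behind the clusters included 310 within 20 kb of reference gene models that were not counted. Such genes carried part of the likeness between nuclei with the same receptor, as given below. The clusters were not remade without them. Among 14268 nuclei of the Orco clusters with a top receptor at 5 or more UMIs, 75.4% ± 0.185 had a 9E receptor, 8.65% ± 0.419 a U receptor, 3.90% ± 0.327 a V receptor and 3.75% ± 0.0330 an E receptor. In cluster 6 the U receptors reached 96.1% ± 0.572, and in cluster 11 the V receptors 92.9% ± 1.26. Clusters 28 and 30 held a single top receptor, Or5-9E254, in 44 of 44 and 41 of 41 nuclei. Clusters 4 and 8 were mixed, with 20.9% ± 0.136 and 21% ± 0.426 E receptors beside 25.2% ± 1.25 and 32.9% ± 1.33 9E receptors.

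**Figure D5:**
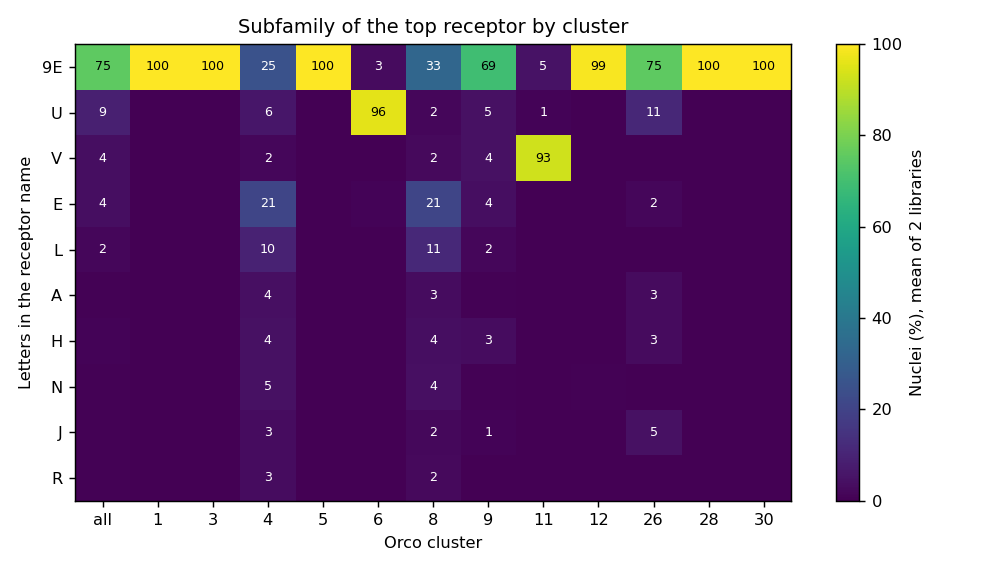
Share of nuclei (percent, mean of 2 libraries, colour scale and numbers of 1 or more) by the subfamily of their top receptor at 5 or more UMIs (vertical axis) in each Orco cluster and in all of them (horizontal axis). Cluster 6 has 96.1% U receptors and cluster 11 has 92.9% V receptors.

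The last question on receptors was whether nuclei with the same receptor also resembled each other in the rest of their genes. They did so more than shuffled nuclei. Of the 15 nearest neighbours of a nucleus in the opposite library, by components made without the listed genes, 5.25% ± 0.0159 had the same top receptor, against 0.339% ± 0.0139 with shuffled receptors. A top receptor of the same run was found in 49.6% ± 0.970 against 11.6% ± 0.0879, and one of the same subfamily in 82.3% ± 0.438 against 54.1% ± 0.0820. No test was run on these shares, since nuclei are not replicates. The share with the same receptor fell to 2.38% ± 0.0084 when genes within 20 kb of gene models missing from the files were left out, and to 1.54% ± 0.0345 with 10 components instead of 30. The share of the same run fell to 24.6% and 25.1% in the 2 libraries and to 27.0%, respectively.

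The other clusters were compared each with the mean of the remaining clusters of the fit. Of 371 odorant receptors tested with edgeR, some were higher in each of the 10, from 5 in cluster 19 and 13 in cluster 17 to 40 in cluster 14 and 63 in cluster 18. Of all 8438 genes tested, 1047, 1356, 1388 and 1083 were higher in these clusters. Only in cluster 18 were receptors higher more often than genes in general. Up to 57 receptors were lower, in cluster 10, where 1563 of all genes were. In cluster 14 (264 nuclei) the ionotropic receptors Ir315.1, Ir315.2PSE and Ir315.3 had log2 fold changes of 7.73 (SE 0.13), 8.09 (SE 0.36) and 8.13 (SE 0.24) and the gustatory receptor Gr7 8.23 (SE 0.82), with edgeR adjusted p of 1.46e-31, 9.98e-20, 3.35e-17 and 1.03e-09. Ir315.1 had 977 and 1130 CPM there in the 2 libraries. The other 6 genes with the largest fitted changes were odorant receptors with 0 UMIs in a cluster in both libraries, so no fold is given: Or5-B1 and Or5-9E31 in cluster 17, Or5-9E149PSE in cluster 18, and Or5-9E190, Or5-9E51 and Or5-9E80 in cluster 19. These clusters had between 395522 and 673721 UMIs per library, and a count of 0 allows up to 3 UMIs.

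Further listed genes were singled out after their values were seen. Gr11 reached 4352 and 6085 CPM in cluster 14 (log2 fold change 7.07, SE 0.09), where Gr2 was also higher (5.59). In cluster 16 Ir75f.3 (6.84), Ir75f.1 (7.19) and Gr25 (4.63) were higher, in cluster 10 Gr10 (5.36), in cluster 19 Obp11 (5.16) and in cluster 7 Csp2 (4.78), all past the edgeR threshold. Markers of ionotropic receptor neurons were found at some level in most clusters. No level at which a marker counts had been fixed, so no cluster was named from them, and the 3 with the highest values are given here. Cluster 14 had 474 CPM of Ir8a and 38.8 of Ir25a.2, cluster 16 had 621 of Ir93a and 204 of Ir8a, and cluster 23, with 91 nuclei and not in the fit, had 86.3 of Ir76b, 88.5 of Ir8a and 61.9 of Ir25a.2. Among lower values were 28.5 of Ir93a in Orco cluster 9, 28.2 in the low-UMI cluster, 25.3 of Ir25a.2 in cluster 15, and 18.3 and 17.1 of Ir76b in cluster 21 and Orco cluster 8. Of these markers 2 took part in the clustering.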

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

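The cluster of nuclei with few UMIs belongs to no comparison, and its values were looked at only after the clusters had been seen. The 4295 nuclei of this low-UMI cluster had 365 ± 41.6 Orco CPM (SD, n = 2 libraries), as high as the Orco clusters with 331 ± 11.3. The other clusters had 92.5 ± 9.84. A count of 0 would allow 1.29 and 1.11 CPM, a limit for counting error only that does not measure free RNA. Odorant receptors took 12862 ± 255 CPM in the low-UMI cluster, between the other clusters and the Orco clusters. At 5 or more UMIs a receptor was called in 2.47% and 2.03% of its nuclei, with a median of 1073 and 1066 UMIs per nucleus. At 2 or more UMIs the share was 44.0% ± 0.911, against 36.6% ± 0.707 after thinning to 1000 UMIs, a depth at which the Orco clusters had 85.6%. Thinning left out the nuclei with fewer UMIs, 490 of 1980 and 690 of 2315 here. Csp genes took 941 CPM in it, over both libraries together, and the median mitochondrial share was 0.354%. No explanation of this cluster was tested.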

How the results depend on the processing

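The limits of 5 and 10 UMIs, the scrublet, Orco limit and all-chemosensory alternatives, leaving out Orco cluster 9, and the runs split by subfamily were chosen after seeing the data. Of 76 alternative values apart from the 1-sided difference, 46 stayed within the spread of the libraries or within 1.5 times a count, and 30 moved. Some of the 46 could not move. The values with 1 library left out always lie within the SD of both. Splitting runs by subfamily cannot change the share of nuclei with a receptor or with 2 or more. The 1-sided difference passed its permutation test in all 12 alternatives run, but its size, 28.9 points ± 0.198, moved (13.5 to 31.9 points, permutation p 1e-05, the smallest possible, to 0.0007). It is oriented by the other library, so a value above 0 and this test show only that the libraries agree on the side. The libraries had the same sign in 17 of 19 runs at 2 or more UMIs and in 12 of 18 at 10 or more.

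The number of UMIs needed for a call moved every other receptor value, in the order of 1, 3, 5 and 10 UMIs. The share of nuclei with a receptor was 99.99%, 92.2%, 81.6% and 57.0%, and the share of these with 2 or more 99.97%, 81.3%, 66.7% and 42.1%. Pairs from 1 run made up 43.1%, 88.5%, 91.9% and 92.1%, and unbroken stretches 5.64%, 25.8%, 36.5% and 53.3%. Neighbours with the same top receptor were 5.38% at 3 UMIs and 5.67% at 5 UMIs, 5.90% with 5 neighbours and 1.54% with 10 principal components. The cause was not tested.

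The share of nuclei with a receptor moved little, to 97.3% with 1000 UMIs per nucleus, 97.2% at resolution 0.5, 97.0% at resolution 2, 97.4% without the top 8% of scrublet scores, 97.2% with an Orco limit of 150 and 97.1% with all chemosensory genes out of the clustering. Pairs from 1 run were 79.9% without the top 8% of scrublet scores, and unbroken stretches 16.9% with runs split by subfamily. Leaving out 1 library gave 97.2% to 97.3%, 92.1% to 92.9%, 77.4% to 78.0% and 17.6% to 17.7% for the 4 receptor shares.

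With edgeR, 4402 genes differed and 343 odorant receptors were higher. Without a filter the counts were 5109 and 523, since more genes were tested. With 1 sum of all other clusters as reference they were 7536 and 509, from 11397 genes tested and 2 classes in the fit. Without the replicate block the counts were 4420 and 344, and with DESeq2 4402, of which 2013 were higher, and 329. Without Orco cluster 9 they were 4579 and 352. The other alternatives gave 3940 to 4429 genes and 299 to 342 receptors. Leaving out a library leaves no test, gap lengths and strand could not be varied, and keeping doublets changed nothing as none was called. The depth of about 3000 UMIs per nucleus limits calls at 5 or more UMIs.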

Other observations

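The tests below of free RNA, doublets, reads shared between neighbours of different and of the same subfamilies, and a shared side of neighbouring receptors were chosen only after the result was seen, as were the genes of the first paragraph. Some odorant receptors were higher in clusters with little Orco. In cluster 20 (172 nuclei) Or5-A4 had 184 and 122 CPM in the 2 libraries (log2 fold change 7.42, SE 0.46), Or5-B1 192 and 287 (5.21, SE 0.42) and Or5-A5 50.1 and 45.5 (4.95, SE 0.56). In cluster 7 (1269 nuclei) Or5-A4 had 27.6 and 30.9 (4.94, SE 0.42). Cluster 20 had 99 Orco CPM over both libraries and cluster 7 98.9, close to the 92.5 ± 9.84 of all other clusters. Obp10, an odorant-binding protein, was higher in cluster 18 (3.43, SE 0.16), with 208 and 171 CPM. In cluster 13 Or5-H6PSE had 63 UMIs in library 1 and 744 in library 2, so its change there rests on 1 library.

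The first pattern was that receptors of 1 run were called together. Free RNA drawn at random would give a share near the shuffled one. In simulated nuclei at 2 or more UMIs it was 61.9% against 62.0% shuffled with free RNA only. With 1 receptor plus free RNA it was 37.1% against 35.3%. In the Orco clusters, pairs from 1 run made up 77.7% at that limit, against a highest shuffle of 20.5%. Doublets would join random receptors, and at 5 or more UMIs without the top 8% of scrublet scores the share was 94.0% against 12.3% for the top receptors of random pairs of nuclei. Reads shared between paralogs stay open: consecutive receptors of 1 subfamily overlapped with a median Jaccard index of 24.8%, and without sequences likeness and position cannot be told apart. Consecutive receptors of different subfamilies had a median of 0%, but 7 of 19 pairs in library 1 and 6 of 15 in library 2 lay above the 95th percentile of pairs of 1 subfamily from different runs. That percentile was 0%, so any overlap counted. Examples are Or5-Y1 and Or5-P1 with 55.9% and 65.8%, but also Or5-M2 and Or5-N1 with 4.55% in library 1 and Or5-O3 and Or5-P7 with 4% in library 2. The median thus decides nothing. With at least 20 nuclei per receptor instead of 5, the limit first used, 2 pairs were left with a median of 48.4%. These were Or5-N2 with Or5-Y1 and Or5-Y1 with Or5-P1, which share a receptor.

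The second pattern was that the calls beside the top receptor lay mainly on 1 side. Unequal free RNA of the neighbours is argued against at 5 or more UMIs only. There the mean difference per receptor was 35.7 points after each neighbour's share in nuclei of other runs was taken off and 35.6 before. At 2 or more UMIs, where free RNA weighs more, this was not tested. Equal sharing of reads within a pair is not decided. Within 119 consecutive pairs the share with the second when the first was top and the reverse differed by 40.1 points ± 0.633. In 101 pairs the sign was alike in both libraries. The 2 receptors of a pair were not matched by their UMIs when top. With equal sharing, the one with more UMIs would bring its neighbour past the limit more often. Consecutive pairs share receptors, so sign flips were made over the 13 runs of these pairs, a unit chosen after the result was seen, where the mean was 30.1 points ± 0.487 (permutation p = 0.00042, above 0 in 12 runs). Sharing of reads, equal or unequal, and transcripts that run past the annotated end of a gene into its neighbour stay open. No biological explanation was tested, since the design has 1 group. A hypothesis is that the side may be set for stretches of receptors rather than for each: 67.9% of consecutive receptors had the same side at 5 or more UMIs, against a mean of 59.2% in 1000 shuffles within runs, of which 27 reached it. At 2 or more UMIs it was 83.2% against 71.1%, which 0 of 1000 reached.

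The third pattern was that nuclei with the same top receptor were neighbours by their other genes. Transcripts that reach into genes beside the receptors could give this, so genes within 20 kb of the 588 protein-coding models of the reference that the files lack were left out, as a stand-in for genes beside receptors. The share with the same receptor fell to 2.38% ± 0.0084 from 5.25%, and it was 5.23% ± 0.0012 with as many variable genes left out at random. More of the excess over the shuffled 0.339% was thus lost than kept, in line with a part played by such genes. The rest stays open, since the stand-in may miss receptor neighbours and no biological explanation was tested.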
